A study of Mus musculus with 12 samples.

How the data were processed

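RNA sequencing libraries came from primary podocytes, the epithelial cells that cover the glomerular capillaries and carry the slit diaphragm of the kidney filter. The mice were in a diabetes model of high-fat diet and streptozotocin. Knockout mice carried a Cre transgene acting in podocytes and floxed Nsd2 alleles, and control mice carried the floxed alleles without Cre. Podocytes were taken at 20 or 28 weeks of age, which gave 4 groups of 3 libraries, 12 in all. Per the labels' protocols, RNA was extracted with a Qiagen RNeasy kit and libraries were made with a SMARTER mRNA kit, and the labels give all libraries the same batch. The labels do not state that the 3 libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical.

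The authors deposited a table of raw read counts per gene symbol for each age, per the file headers. The authors also deposited an FPKM table for each age, which divides each count by a gene length and by the column total of the same count table. The length implied by the FPKM values was the same across the 6 libraries of every gene, within a relative tolerance of 1e-06. Per the submitters' processing notes, the genome build was GRCm38 (mm10). The aligner, the counting program, its strand setting and the annotation are not given in the sources used here. The tables listed 23829 genes at 20 weeks and 23777 at 28 weeks, with 22290 in both; genes without a read in any library of an age are not listed. The highest total count of a gene listed at 1 age alone was 13 at 20 weeks and 15 at 28 weeks. Total counts per library ran from 31405349 to 38989180, and at 28 weeks all 3 knockout libraries had lower totals than the controls. At this depth a gene with 0 reads in a library could still have a level of up to between 0.0769 and 0.0955 counts-per-million (CPM), taking 3 counts as the limit that 0 allows. PCR copies cannot be recognised in counts, so limits and intervals from counts cover counting error only.

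Each age was fitted alone with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr with default settings on the group factor, and the quasi-likelihood F test without a block. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested at that age. All adjusted p-values of single genes are from this test unless another tool is named. Standard errors of log2 fold changes were taken as the fold change divided by the square root of F. CPM values used the TMM-scaled library sizes. The change of the knockout effect between ages, and the change with age within controls and within knockouts, were contrasts of 1 edgeR model of all 12 libraries over the genes in both tables. Age coincides with the deposited table, so a difference in handling between the tables would be part of these contrasts. Overlap of calls between the ages was tested with Fisher's exact test, two-sided, per direction; the comparisons at 20 and 28 weeks share no library.

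Before the data were examined, 23 gene lists were fixed, for podocyte identity, Hippo core, YAP/TAZ targets, extracellular matrix, actin and adhesion, inflammation and NF-kB, interferon response, cell cycle, p53 with apoptosis and senescence, endoplasmic reticulum stress, oxidative phosphorylation, fatty acid and lipid metabolism, glycolysis, histone lysine methylation enzymes, endothelial, mesangial and fibroblast, tubule, parietal epithelial, leukocyte and red blood cell markers, immediate early and heat shock genes, mitochondrially encoded genes and ribosomal proteins. Lists with at least 5 tested members were tested with camera (limma 3.58.1), which compares a list with all other genes, at a preset correlation of 0.01 between genes, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. For each list the calls over all genes and the calls adjusted over the list alone were counted. A further 5 lists, for epithelial junctions and keratins, the loop of Henle with distal tubule and collecting duct, the proximal tubule, smooth muscle contraction, and pericytes with mesangium, were written after the calls had been seen. Since these 5 lists were written from the calls in these same data, their p-values only describe them and test nothing. The comparisons of lists between the ages were also added after the data had been seen.

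Genes were named by a rule fixed before the data were examined. It takes Nsd2; the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 5 CPM and no overlap between the groups, passing over predicted and unnamed genes; up to 4 called members of each list with the smallest p, or up to 2 as values where none was called; and Yap1, Wwtr1, Lats1, Lats2, Stk3, Stk4, Ccn1, Ccn2, Nphs1, Wt1, Synpo and Podxl whatever their p. Some genes that met the rule are not reported here. For the joint contrasts, in which no gene was called, it takes the 3 genes with the smallest p as values. With 3 libraries against 3, chance alone leaves the groups without overlap in 10% of genes on average, if the libraries are separate samples. Of 150 named genes, 148 had a place in the GENCODE M21 annotation of GRCm38. Of these, 44 shared exon bases with another gene, 38 of them only with a gene on the other strand, and their counts are uncertain to that extent because the strand setting is not known.

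Alternatives fixed before the data were examined were size factors by the median of ratios, upper-quartile scaling, no filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, a robust estimate of the spread, the replicate number as a block, a fold change of at least 2, limma on log2(FPKM + 1) of genes with an FPKM of at least 1 in 3 libraries, the joint model of 12 libraries, and leaving out each library in turn. Added after the data had been seen were counting the alike control libraries 2 and 3 at 28 weeks as their sum, and leaving out knockout library 1, and the tests of single lists without each library. Libraries of a group were compared pairwise by chi-square over genes with at least 20 counts and by their biological coefficient of variation (BCV) over genes with a mean of at least 10 counts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

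The edgeR step was tested on simulated data, with 200 genes changed by known folds in counts drawn from the real means and library sizes. At 20 weeks, over 14853 genes, it recovered 22.2% of 2-fold, 82.2% of 4-fold and 92.7% of 8-fold changes, with 6 false calls among 133. At 28 weeks, over 15011 genes, the shares were 11.3%, 75.7% and 89.1%, with 7 false calls among 120. For the change of the knockout effect between the ages, over 15662 genes, they were 6.78%, 56.8% and 86.6%, with 1 false call among 105. The simulation drew each gene independently, changed only 200 genes and held no alike pair of libraries. The real fits called 1473 genes at 20 weeks and 3183 at 28 weeks. These shares and false calls thus describe the simulated setting and cannot be carried over to the real calls.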

Results

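Gene expression was measured by RNA sequencing in podocytes isolated from diabetic mice with or without a podocyte knockout of Nsd2, a histone methyltransferase that places dimethyl marks on lysine 36 of histone H3. The series asks how loss of this enzyme in podocytes, the epithelial cells of the glomerular filter, alters transcription early and late in diabetic kidney disease, with attention to Hippo signalling. Each of 4 groups held 3 libraries: floxed controls and Nsd2 knockouts at 20 weeks, and the same genotypes at 28 weeks. At 20 weeks the total counts of control libraries 1 to 3 were 35920498, 35684946 and 37751602. Those of knockout libraries 1 to 3 were 37524133, 36871156 and 35664511. At 28 weeks the totals were 38989180, 38970590 and 38625577 in controls and 33086164, 31405349 and 35547010 in knockouts. Levels are given as normalised counts-per-million (CPM), mean ± SD over 3 libraries, and fold changes as log2 of knockout over control with the standard error (SE).

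Nsd2 was lower in every knockout library than in any control of its age. At 20 weeks the control libraries held 94.2, 66.6 and 79.0 CPM and the knockouts 51.7, 34.1 and 45.0 CPM, a log2 fold change of -0.88 (SE 0.21, n = 3 per group, adjusted p = 0.0402). At 28 weeks the levels were 87.2, 77.6 and 80.1 CPM in controls and 35.2, 35.2 and 42.9 CPM in knockouts, a log2 fold change of -1.11 (SE 0.13, n = 3 per group, adjusted p = 0.00431). The transcript was reduced but not lost: mean levels were 43.6 ± 8.91 CPM in the knockouts against 79.9 ± 13.8 CPM in controls at 20 weeks, and 37.8 ± 4.41 against 81.6 ± 4.96 CPM at 28 weeks. Counts per gene do not show which exons were read, and the position of the floxed part is not given in the sources used here. Nsd2 lies on chromosome 5 at 33820725 to 33897975, plus strand, in the GRCm38 build with GENCODE M21 annotation, and shares exon bases with Nelfa on the other strand. The call at 20 weeks ended without control library 1 (-0.75, adjusted p = 0.164), control 2 (-0.98, 0.0729), control 3 (-0.88, 0.0903), knockout 2 (-0.72, 0.0903) or knockout 3 (-0.88, 0.111), and with a filter of 1 CPM in 3 libraries (-0.93, 0.0562). The call at 28 weeks was kept without each library, with a log2 fold change between -1.26 and -1.06.

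**Figure D1:**
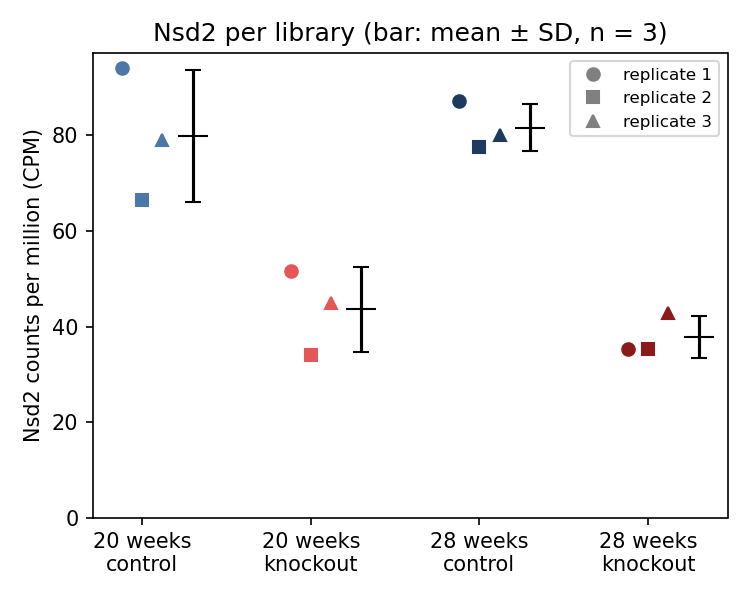
Nsd2 in normalised counts-per-million in each of the 12 libraries (points), with the group mean (bar) and SD (error bar) of 3 libraries. All knockout libraries lie between 34.1 and 51.7 CPM and all controls between 66.6 and 94.2 CPM.

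The first principal component, 52.7% of the variance, separated the genotypes at both ages. Controls lay between -76.5 and -48.0 on it and knockouts between 8.33 and 91.0. Knockout library 1 of each age stood nearest the controls, at 23.1 at 20 weeks and 8.33 at 28 weeks, and the other 4 knockout libraries lay between 53.9 and 91.0. Control libraries 2 and 3 at 28 weeks were more alike than any other pair of 1 group, with a BCV of 0.0474 against 0.228 to 0.413 in the other 11 pairs. Their counts differed by more than sampling noise (mean chi-square 4.56 over genes, against 1 for noise alone), so they were not counted as 1 library. That does not exclude 1 RNA or 1 animal prepared as both, and the labels do not state that they came from separate animals. With their counts summed, 1299 genes were called at 28 weeks in place of 3183. The SDs, SEs and p-values of single genes at 28 weeks count both libraries, and can be too small if these came from 1 animal.

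**Figure D2:**
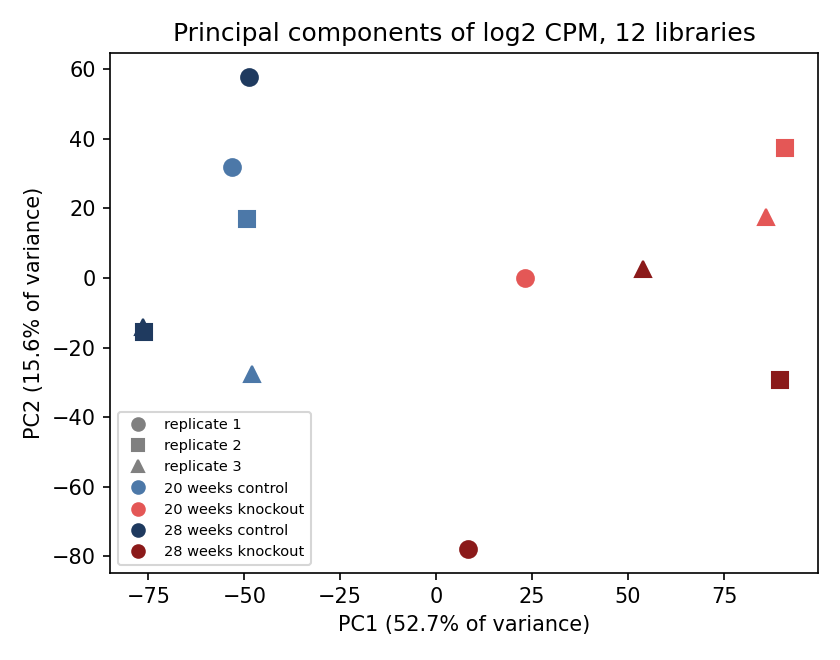
Principal components 1 (52.7% of variance) and 2 (15.6%) of log2 CPM, 1 point per library, by genotype and age. Controls lie between -76.5 and -48.0 on component 1, and knockout library 1 of each age (23.1 and 8.33) lies between the controls and the other knockouts.

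The first comparison asks which transcripts differ between Nsd2 knockout and control podocytes at 20 weeks, the early stage. The genes that rose in the knockouts included genes of contractile and perivascular cells. Myh11, the heavy chain of smooth muscle myosin, went from 6.97 ± 0.503 to 68.0 ± 5.45 CPM (log2 3.29, SE 0.17, adjusted p = 0.000668, n = 3 per group). Rgs5, a regulator of G protein signalling marking pericytes, went from 18.3 ± 4.94 to 220.3 ± 108 CPM (log2 3.59, SE 0.38, adjusted p = 0.00292). C3, the central complement component, went from 12.6 ± 6.67 to 138 ± 13.4 CPM (log2 3.46, SE 0.42, adjusted p = 0.00411). C1s1, a protease gene of the same system, went from 33.4 ± 10.1 to 307 ± 50.1 CPM (log2 3.20, SE 0.27, adjusted p = 0.00241). Cdo1, which encodes cysteine dioxygenase, had the largest rise of the named genes, from 4.32 ± 0.823 to 89.9 ± 47.5 CPM (log2 4.38, SE 0.46, adjusted p = 0.0029). The genes that fell included some of tubule and simple epithelial cells. Mal, a protein of apical membrane traffic in tubule cells, was at 467 ± 202 CPM in controls and 11.1 ± 2.97 in knockouts (log2 -5.39, SE 0.39, adjusted p = 0.0017). The simple epithelial keratin Krt7 was at 970.1 ± 482 and 51.7 ± 20.7 CPM (log2 -4.23, SE 0.44, adjusted p = 0.0028).

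The other genes with the highest folds at 20 weeks were Ptn, a heparin-binding growth factor (log2 3.61), the collagen receptor subunit Itga11 (3.56), the ATP-gated channel P2rx1 (3.20), the chemokine receptor Ackr3 (3.19) and Cbr2, a carbonyl reductase (3.00), with adjusted p between 0.00286 and 0.00443. Several of the genes that fell came close to 0 in the knockouts. Plekhs1 went from 83.7 ± 22.6 to 0.0922 ± 0.16 CPM (adjusted p = 0.00231). The chemokine Ccl20 went from 49.8 ± 31.3 to 0.0922 ± 0.16 CPM (adjusted p = 0.00322) and the platelet chemokine Ppbp from 47.4 ± 21.9 to 0.157 ± 0.248 CPM (adjusted p = 0.00319). Il5ra, a receptor subunit for interleukin 5, had 2760 counts over the controls and 2 over the knockouts, a ratio of 1303 with an exact 95% counting interval of 360.5 to 10768 (adjusted p = 0.00272). All knockout counts of Plekhs1, Ccl20 and Il5ra were in knockout library 1. Without it these genes were at least 1959-fold, 1174-fold and 574-fold lower, with a floor of 3 counts over the other knockouts. Ppbp then had 1 knockout count, a ratio of 3318 (595 to 131063). Rab25, Pak6, Cblc, Mab21l4 and Spaca7 were also among the lowest, with adjusted p between 0.0145 and 0.0286. Each lost its call without 2 or more of the 6 libraries. Without knockout 1 the log2 fold change went from -5.26 to -6.03 for Rab25 and from -5.01 to -6.20 for Pak6. Cblc and Mab21l4 then had 1 knockout count each, a ratio of 2045 (367 to 80802) and of 2589.9 (465 to 102322), and Spaca7 had 0, at least 333-fold lower with the same floor.

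Of 30 podocyte identity genes measured at 20 weeks, 14 rose, 1 fell and 15 did not pass (20 rose and 2 fell adjusted over the list alone). Their median log2 fold change was 0.89 (camera, adjusted p = 1.31e-09, and adjusted p = 0.385 with an estimated correlation). In the same libraries genes of other epithelia had negative medians: -1.71 for parietal markers and, in lists written after the calls had been seen, -2.36 for junction and keratin genes and -3.97 for genes of the loop of Henle, distal tubule and collecting duct. Clic5, a chloride channel protein of foot processes, rose from 102 ± 42.9 to 558 ± 148 CPM (log2 2.45, SE 0.33, adjusted p = 0.00574). Col4a5, a chain of the glomerular basement membrane collagen, rose from 131 ± 32.2 to 333 ± 14.9 CPM (log2 1.34, SE 0.20, adjusted p = 0.00826). Calls of Synpo (log2 1.58), Podxl (1.39) and Wt1 (1.05) depended on single libraries. That of Synpo ended without control 2 (adjusted p = 0.0508). The call of Podxl ended without control 2 (0.0871), knockout 2 (0.0789) or knockout 3 (0.0744), and that of Wt1 without controls 2 (0.118) or 3 (0.1) or knockouts 2 or 3 (0.105 in both). In the model of all 12 libraries their adjusted p were 0.16, 0.0665 and 0.124. Nphs1, which encodes nephrin, was low in both groups (4.6 ± 3.03 and 4.82 ± 2.86 CPM, adjusted p = 0.968). In controls 1 to 3 Krt18 was at 803, 1620 and 751 CPM and Acta2 at 1599, 1671 and 1981 CPM. Podxl was at 354, 242 and 154 CPM there and Synpo at 185, 118 and 106 CPM. The share of podocytes in the preparations was not measured here, so changes cannot be assigned to podocytes alone.

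Of 33 Hippo core genes measured at 20 weeks, 2 rose and 31 did not pass (1 rose adjusted over the list alone), with a median log2 fold change of 0.07 (camera, adjusted p = 0.417). The risen genes were the protocadherins Fat4 (log2 1.57, SE 0.28, adjusted p = 0.0128) and Fat1 (0.69, SE 0.17, adjusted p = 0.0387). The call of Fat4 ended without control 2 (adjusted p = 0.0553) or knockout 3 (0.0562) and in the model of 12 libraries (0.0978). That of Fat1 ended without control 1 (0.0598), 2 (0.147) or 3 (0.102), without knockout 2 (0.0865) or 3 (0.113), and with the 1 CPM filter (0.0567), FPKM values (0.0542) or the model of 12 libraries (0.221). The coactivators Yap1 (log2 0.32, adjusted p = 0.229) and Wwtr1 (0.36, 0.203) and the kinases Lats1 (-0.11, 0.861), Lats2 (0.54, 0.165), Stk3 (0.24, 0.721) and Stk4 (-0.11, 0.716) did not pass. Among 22 YAP/TAZ targets, 5 rose and 2 fell (7 and 2 adjusted over the list alone), with a median of 0.51 (camera, adjusted p = 0.00119, and adjusted p = 0.279 with an estimated correlation). Igfbp3, a binding protein of insulin-like growth factors, rose from 28.7 ± 4.18 to 107 ± 11.0 CPM (log2 1.90, SE 0.18, adjusted p = 0.00272). The growth factor Tgfb2 rose from 44.6 ± 2.57 to 96.3 ± 9.7 CPM (log2 1.11, SE 0.16, adjusted p = 0.0066). The matricellular gene Ccn2 was called (log2 0.78, adjusted p = 0.0204) and Ccn1 did not pass (log2 0.38, adjusted p = 0.431). The call of Ccn2 ended without control 2 (0.0632), control 3 (0.0558), knockout 2 (0.0779) or knockout 3 (0.0619) and in the model of 12 libraries (0.128).

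Of 25 matrix genes measured at 20 weeks, 12 rose and 13 did not pass (16 rose and 1 fell adjusted over the list alone). Their median log2 fold change was 1.25 (camera, adjusted p = 1.55e-14, and adjusted p = 0.327 with an estimated correlation). The proteoglycan Bgn rose from 165 ± 63.9 to 982 ± 112 CPM (log2 2.57, SE 0.31, adjusted p = 0.00383). The fibrillar collagen Col5a2 rose from 301 ± 48.8 to 849 ± 60.1 CPM (log2 1.5, SE 0.18, adjusted p = 0.00383). Of 12 mesangial and fibroblast markers 7 rose and 1 fell (the same numbers adjusted over the list alone; median 1.03, camera adjusted p = 2.85e-05, and adjusted p = 0.279 with an estimated correlation). Acta2, smooth muscle actin, went from 1750.3 ± 203 to 4975 ± 639 CPM (log2 1.51, SE 0.17, adjusted p = 0.00346). Tagln, an actin-binding protein of smooth muscle, went from 2409 ± 91.5 to 5616 ± 1337 CPM (log2 1.22, SE 0.20, adjusted p = 0.0105). Actin and adhesion genes had 3 risen of 20 (7 adjusted over the list alone; median 0.29, camera adjusted p = 0.00283 and adjusted p = 0.327 with an estimated correlation). A list of smooth muscle contractile genes written after the calls had been seen had 10 risen of 17 (median 1.06, camera adjusted p = 1.11e-20 and adjusted p = 0.0141 with an estimated correlation). A second such list, of pericyte and mesangial genes, had 9 risen and 1 fallen of 13 (median 1.13, camera adjusted p = 1.96e-10 and adjusted p = 0.0141 with an estimated correlation). Both lists were written from calls in these same libraries, so their p-values test nothing, also where they pass with an estimated correlation.

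All calls in the lists of epithelia other than podocytes were downward at 20 weeks. Of 8 parietal epithelial markers, which include keratins, 4 fell and 4 did not pass (4 adjusted over the list alone; median -1.71, camera adjusted p = 2.85e-05, and adjusted p = 0.327 with an estimated correlation). The tubule list had 1 fallen of 6 tested (1 adjusted over the list alone; median -1.15, camera adjusted p = 0.133), and passed without control 2 (0.0158), control 3 (0.00975) or knockout 1 (0.000258). Among 3 further lists written after the calls had been seen, epithelial junction and keratin genes had 10 fallen of 25, all 25 with negative values (median -2.36, camera adjusted p = 5.01e-16 and adjusted p = 0.0745 with an estimated correlation). Genes of the loop of Henle, distal tubule and collecting duct had 9 fallen of 18 (median -3.97, camera adjusted p = 2.67e-16 and adjusted p = 0.0497 with an estimated correlation). Proximal tubule genes had 2 fallen of 8 (median -1.05, camera adjusted p = 0.0307 and adjusted p = 0.264 with an estimated correlation). These 3 lists were written from calls in these same data, so their p-values test nothing. The knockout libraries differed among themselves here: median log2 differences from the control mean over the junction and keratin list were -1.14, -3.99 and -3.96 in knockouts 1 to 3. Cdh1, which encodes E-cadherin, was at 251, 9.96 and 12.8 CPM in these libraries and at 291, 160.3 and 340.1 CPM in the controls.

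**Figure D3:**
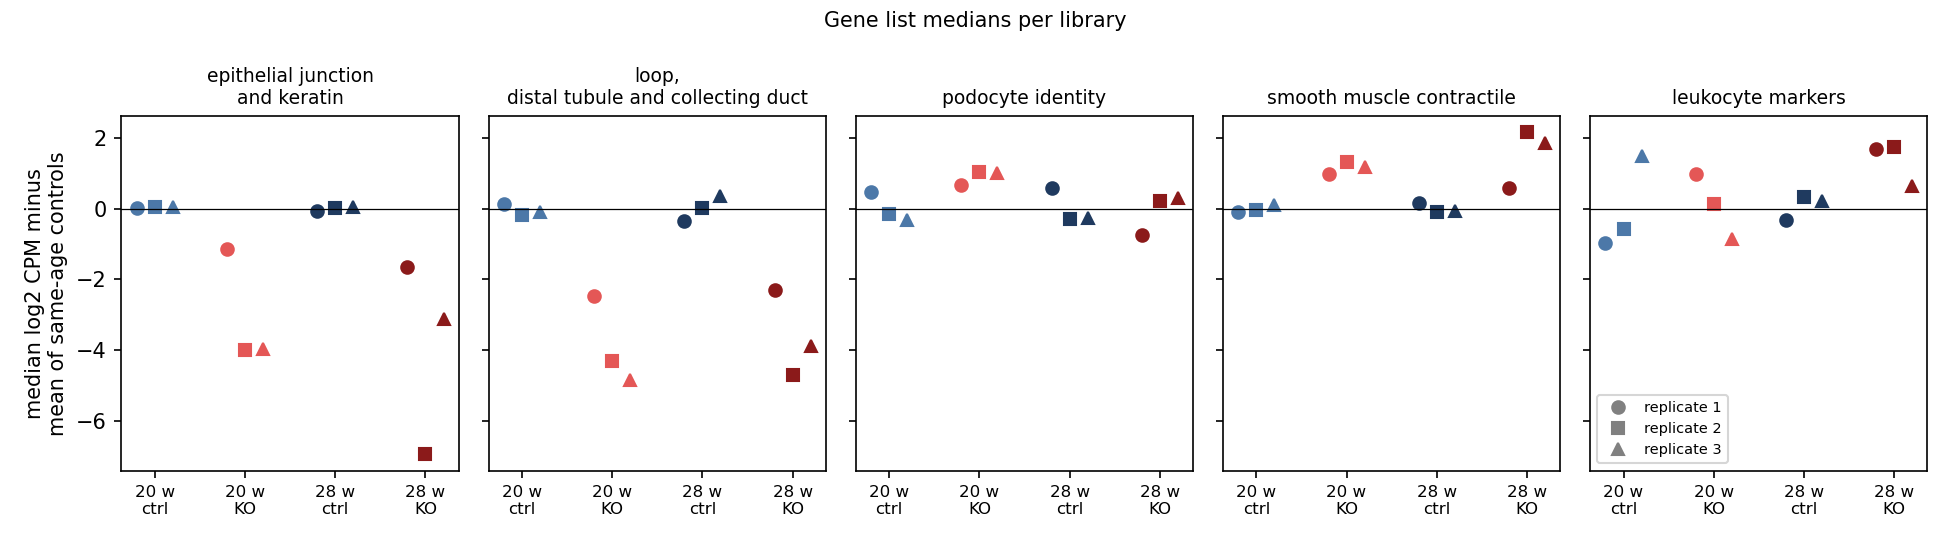
Median log2 CPM of each gene list in each library, minus the mean of the controls of the same age, 1 point per library. In the epithelial junction and keratin list the knockouts lie at -1.14, -3.99 and -3.96 at 20 weeks and at -1.66, -6.93 and -3.10 at 28 weeks.

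Stress and metabolic lists were also tested at 20 weeks. Of 20 genes of p53, apoptosis and senescence, 1 rose and 5 fell (1 and 6 adjusted over the list alone; median -0.54, camera adjusted p = 0.00372 and adjusted p = 0.385 with an estimated correlation). The risen gene was the death receptor Fas (7.5 ± 0.775 to 27.6 ± 3.01 CPM, log2 1.88, SE 0.19, adjusted p = 0.00272). Among the fallen was Mdm2, the ubiquitin ligase that limits p53 (386 ± 30.4 to 198 ± 17.2 CPM, log2 -0.97, SE 0.15, adjusted p = 0.00948). All 18 ribosomal protein genes had negative values (median -0.46, camera adjusted p = 0.000425 and adjusted p = 0.682 with an estimated correlation), although 0 were called over all genes and 0 adjusted over the list alone. Lists that did not pass were, with calls up and down: inflammatory and NF-kB genes (1 and 4 of 20; 2 and 6 adjusted over the list alone; camera adjusted p = 0.122), interferon response (2 and 0 of 18; 6 and 3; 0.265), cell cycle (0 of 24; 0; 0.293), endoplasmic reticulum stress (1 and 1 of 13; 1 and 1; 0.721) and oxidative phosphorylation (0 and 1 of 18; 0; 0.417). Fatty acid and lipid genes had 2 up and 2 down of 20 (the same adjusted over the list alone; median 0.17, mean -0.02, camera adjusted p = 0.701). Hadha, a subunit of the mitochondrial fatty acid oxidation enzyme, fell from 118 ± 13.7 to 50.7 ± 9.04 CPM (log2 -1.22, SE 0.19, adjusted p = 0.00901). Glycolysis (0 and 1 of 15; 0 adjusted over the list alone; 0.605), histone lysine methylation enzymes (0 of 14; 0; 0.602), endothelial markers (1 and 0 of 12; 1 and 0; 0.417), leukocyte markers (0 of 12; 0; 0.805), immediate early and heat shock genes (0 of 17; 0; 0.438) and mitochondrially encoded genes (0 of 9; 0; 0.331) did not pass either, and none of the red blood cell markers reached the level needed for testing. The call of Ehd3, an endothelial membrane-traffic gene, was the only one in its list (log2 1.5, SE 0.23, adjusted p = 0.00814). Control 3 stood apart in leukocyte genes, with C1qb at 52.3 CPM against 4.28 and 3.03 in controls 1 and 2 and Tyrobp at 17.9 against 2.23 and 2.34 CPM. Without it leukocyte markers passed upward (median 1.14 in place of -0.68, camera adjusted p = 0.00975). Inflammatory and NF-kB genes passed downward without control 3 (0.00201) or knockout 1 (0.00764), and mitochondrially encoded genes upward without knockout 2 (0.00384).

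In all, 1473 of 14853 genes tested were called at 20 weeks, 711 higher and 762 lower, and 3719 had an unadjusted p below 0.05 (edgeR). Of the called genes, 500 were at least 2-fold higher and 673 at least 2-fold lower. Over all genes tested the groups did not overlap in 4789 (32.2%). Chance gives 10% on average over splits, but genes are not independent, so a single split can lie far from it. Without single libraries the count was 517 (control 1), 602 (control 2), 663 (knockout 2) or 553 (knockout 3), and DESeq2 called 2430. Of 67 named genes called, 34 stayed called without each library in turn, and of the 66 besides Nsd2 the fold of 14 moved by over 1.5 times without knockout library 1, with none changing sign.

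The second comparison asks the same question at 28 weeks, the advanced stage. The genes that rose in the knockouts included 3 of 13 leukocyte markers, Lyz2, Adgre1 and Tyrobp. Lyz2, lysozyme of macrophages and neutrophils, went from 49.4 ± 1.43 to 651 ± 140.3 CPM (log2 3.72, SE 0.20, adjusted p = 0.00191). Outside that list, Clec4n, a C-type lectin receptor of myeloid cells, went from 1.37 ± 0.58 to 20.2 ± 6.6 CPM (log2 3.87, SE 0.41, adjusted p = 0.00371). The monocyte chemokine Ccl7 rose from 1.53 ± 0.487 to 32 ± 20.7 CPM (log2 4.38, SE 0.66, adjusted p = 0.00742). Msln, the surface protein mesothelin, fell from 129 ± 30.5 to 1.90 ± 0.849 CPM (log2 -6.08, SE 0.41, adjusted p = 0.002). Itga3, the laminin-binding integrin of podocytes, fell from 935 ± 179 to 217 ± 34.3 CPM (log2 -2.11, SE 0.20, adjusted p = 0.00319).

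Further risen genes at 28 weeks were Tmem45a (log2 3.62), the choline transporter Slc5a7 (3.61) and the interferon-induced GTPase Tgtp1 (3.59), with adjusted p between 0.00296 and 0.00345. Among the lowest genes, the cytokine Il24 had 1441 counts over the controls and 2 over the knockouts, a ratio of 584 with an exact 95% counting interval of 161 to 4828 (adjusted p = 0.00191). The lipid phosphatase gene Sgpp2 had 1702 and 3, a ratio of 459.9 (157 to 2232, adjusted p = 0.0021), and without knockout 1 a ratio of 927 (166 to 36644). Il5ra fell from 31.7 ± 6.05 to 0.342 ± 0.377 CPM (adjusted p = 0.00392), Ppbp from 48.3 ± 12.3 to 0.543 ± 0.467 CPM (0.00393). Mab21l4 went from 51.8 ± 1.62 to 0.412 ± 0.412 CPM (0.00296) and the tight junction gene Cldn19 from 10.8 ± 0.696 to 0.158 ± 0.144 CPM (0.0035). The potassium channel gene Kcnq1 and the calcium-binding Hpcal4 were likewise near 0 in the knockouts, at 0.21 and 0.209 CPM (adjusted p = 0.00607 and 0.00686).

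Podocyte identity genes at 28 weeks had 0 risen and 4 fallen of 30 (the same adjusted over the list alone). Their median log2 fold change was -0.10 (camera, adjusted p = 0.356). Of all 15011 genes tested at this age 1783 fell, so 4 fallen of 30 lies near the share over all genes. Besides Itga3, the cell cycle inhibitor Cdkn1c fell from 58.0 ± 3.79 to 16.9 ± 7.22 CPM (log2 -1.78, SE 0.31, adjusted p = 0.0108). The calls of Nphs1 (10.7 ± 3.89 to 1.95 ± 1.36 CPM, adjusted p = 0.024) and of the adaptor gene Cd2ap (log2 -1.38, adjusted p = 0.0368) depended on single libraries. Without controls 1, 2 and 3 the adjusted p was 0.0686, 0.0601 and 0.063 for Nphs1 and 0.0953, 0.0927 and 0.0987 for Cd2ap, and without knockout 3 that of Cd2ap was 0.0782. Without knockout 2 the log2 fold change of Nphs1 went from -2.46 to -3.20. Wt1 (log2 0.48, adjusted p = 0.498), Synpo (0.17, 0.909) and Podxl (-0.30, 0.697) did not pass. Synpo was uneven within both groups. It was at 367, 99.2 and 99.7 CPM in controls 1 to 3 and at 48.6, 322 and 265 CPM in knockouts 1 to 3. In the same order Podxl was at 582, 286 and 297 CPM and at 149, 437 and 362 CPM. Krt8 ran the other way, at 111, 2352 and 2376 CPM and at 5545, 29.9 and 196 CPM. Cdh1 in the controls did not (805, 509 and 521 CPM). Whether the cell content of each library lay behind these values was not tested.

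In the Hippo core, 5 of 33 genes fell at 28 weeks and none of the 33 rose (5 adjusted over the list alone), with a median log2 fold change of -0.14 (camera, adjusted p = 0.114). Over all 15011 genes tested at this age 1783 fell and 1400 rose, so a few fallen genes would be found in most lists of this size. Wwc1, which encodes the upstream regulator KIBRA, fell from 443 ± 9.04 to 72.5 ± 23.1 CPM (log2 -2.61, SE 0.25, adjusted p = 0.00324). The scaffold Amot, which binds YAP, fell from 198 ± 18.0 to 59.4 ± 16.0 CPM (log2 -1.73, SE 0.22, adjusted p = 0.00539). The transcription factor Tead4 fell from 10.6 ± 0.532 to 3.11 ± 0.513 CPM (log2 -1.76, SE 0.20, adjusted p = 0.00426). Ajuba, a LIM protein that inhibits LATS kinases, fell from 288 ± 16.3 to 144 ± 2.24 CPM (log2 -1.0, SE 0.10, adjusted p = 0.00351). Yap1 (log2 0.23, adjusted p = 0.569), Wwtr1 (0.32, 0.261), Lats1 (-0.44, 0.107), Lats2 (-0.01, 0.983), Stk3 (0.49, 0.196) and Stk4 (-0.19, 0.257) did not pass. The list as a whole passed without a filter on low counts (camera adjusted p = 0.031) or without knockout 3 (0.026). YAP/TAZ targets had 1 risen and 1 fallen of 22 (the same adjusted over the list alone; median 0.01, camera adjusted p = 0.729). The fallen one was Myof, a membrane repair protein (773 ± 77.9 to 312 ± 43.8 CPM, log2 -1.31, SE 0.16, adjusted p = 0.0046). Ccn1 (log2 -0.09, adjusted p = 0.878) and Ccn2 (0.32, 0.595) did not pass.

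Matrix genes at 28 weeks had 7 risen and 2 fallen of 24 (9 and 2 adjusted over the list alone; median 0.96, camera adjusted p = 0.00022 and adjusted p = 0.904 with an estimated correlation). Sparc, a collagen-binding glycoprotein, rose from 2242 ± 438 to 8999 ± 3134 CPM (log2 2.01, SE 0.30, adjusted p = 0.00762). The fibrillar collagen Col3a1 rose from 23.6 ± 10.2 to 202 ± 103 CPM (log2 3.10, SE 0.46, adjusted p = 0.00726). Timp1, a metalloproteinase inhibitor, rose from 139 ± 5.29 to 359 ± 37.6 CPM (log2 1.37, SE 0.12, adjusted p = 0.00296). Mesangial and fibroblast markers had 4 risen and 1 fallen of 12 (the same adjusted over the list alone; median 0.44, camera adjusted p = 0.111). Among them the contractile gene Cnn1 rose from 70.1 ± 8.49 to 282 ± 51.6 CPM (log2 2.01, SE 0.18, adjusted p = 0.00296). Tagln rose from 1583 ± 228 to 5928 ± 1999 CPM (log2 1.90, SE 0.28, adjusted p = 0.00702). Actin and adhesion genes had 4 risen and 2 fallen of 20 (5 and 2 adjusted over the list alone; camera adjusted p = 0.193). The smooth muscle contractile list, written after the calls had been seen, had 10 risen of 17 (median 1.64, camera adjusted p = 2.10e-09 and adjusted p = 0.191 with an estimated correlation). The pericyte and mesangial list had 3 risen and 1 fallen of 15 (median 0.45, camera adjusted p = 0.0649). It was also written after the calls had been seen, so the p-values of both lists test nothing. Medians of the contractile list were 0.57, 2.15 and 1.84 above the control mean in knockouts 1 to 3, and Myh11 was at 2.41, 75.1 and 71.6 CPM in these libraries, against 8.91, 3.59 and 3.54 CPM in controls 1 to 3.

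Immune lists at 28 weeks included 3 risen of 13 leukocyte markers, with 12 of the 13 values positive (3 adjusted over the list alone; median 1.15, camera adjusted p = 0.000429 and adjusted p = 0.438 with an estimated correlation). The value of Csf1r was -0.49 (adjusted p = 0.33). Beside Lyz2, the macrophage receptor gene Adgre1 rose from 1.47 ± 0.27 to 7.31 ± 1.12 CPM (log2 2.31, SE 0.25, adjusted p = 0.00389). The third, Tyrobp, a signalling adaptor of myeloid cells (log2 1.88, adjusted p = 0.0358), lost its call without controls 1 (0.0857), 2 (0.082) or 3 (0.102), without knockouts 1 (0.0743) or 2 (0.116), and in the model of 12 libraries (0.119). Interferon response genes had 4 risen of 18 (4 adjusted over the list alone; median 0.40, camera adjusted p = 0.0517). Isg15, a ubiquitin-like modifier, rose from 4.32 ± 0.219 to 24.7 ± 7.64 CPM (log2 2.51, SE 0.27, adjusted p = 0.00371) and the GTPase Gbp2 from 8.54 ± 0.587 to 24.5 ± 5.54 CPM (log2 1.52, SE 0.20, adjusted p = 0.00584). Inflammatory and NF-kB genes had 4 risen and 1 fallen of 21 (5 and 1 adjusted over the list alone; median 0.42, camera adjusted p = 0.356).

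All calls in these epithelial lists were downward at 28 weeks too. Parietal epithelial markers had 2 fallen of 8 (7 adjusted over the list alone; median -1.67, camera adjusted p = 0.00589 and adjusted p = 0.904 with an estimated correlation). The transcription factor Pax2 fell from 46.5 ± 13.3 to 9.31 ± 3.68 CPM (log2 -2.32, SE 0.37, adjusted p = 0.0089). The tubule list had 1 fallen of 9, Cdh1 (1 adjusted over the list alone; median -0.91, camera adjusted p = 0.126). Of the lists written after the calls had been seen, epithelial junction and keratin genes had 8 fallen of 25 (median -2.54, camera adjusted p = 2.10e-09 and adjusted p = 0.245 with an estimated correlation). Loop, distal tubule and collecting duct genes had 11 fallen of 22 (median -3.14, camera adjusted p = 4.91e-15 and adjusted p = 0.126 with an estimated correlation), and proximal tubule genes 1 fallen of 8 (median -0.63, camera adjusted p = 0.0113 and adjusted p = 0.161 with an estimated correlation). The knockout libraries differed among themselves here too, with medians of -1.66, -6.93 and -3.10 for the junction and keratin list in knockouts 1 to 3. In knockout 1 Krt8 was at 5545 CPM and Epcam at 478 CPM, above controls 1 to 3 (111, 2352 and 2376 CPM for Krt8 and 229, 369.9 and 375 CPM for Epcam). Their levels were 29.9 and 0.527 CPM in knockout 2 and 196 and 39.2 CPM in knockout 3.

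Growth, stress and metabolic lists at 28 weeks did not pass as lists. Genes of p53, apoptosis and senescence had 2 risen and 8 fallen of 20 (3 and 9 adjusted over the list alone; median -0.28, camera adjusted p = 0.126). The stress cytokine Gdf15 fell from 390.1 ± 48.1 to 132 ± 14.3 CPM (log2 -1.57, SE 0.15, adjusted p = 0.00312) and Fas rose from 5.16 ± 0.443 to 32.7 ± 15.2 CPM (log2 2.66, SE 0.39, adjusted p = 0.00705). Fatty acid and lipid genes had 4 risen and 4 fallen of 20 (the same adjusted over the list alone; camera adjusted p = 0.729). The fatty acid receptor Cd36 rose from 2.22 ± 0.259 to 14.7 ± 6.78 CPM (log2 2.72, SE 0.41, adjusted p = 0.00732). Glycolysis genes had 1 risen and 3 fallen of 15 (the same adjusted over the list alone; camera adjusted p = 0.376). Hk2, a hexokinase, fell from 148 ± 32.5 to 32.1 ± 11.4 CPM (log2 -2.20, SE 0.29, adjusted p = 0.00602). The histone lysine methylation enzymes had 2 fallen of 14 and 13 negative values (5 fallen adjusted over the list alone; median -0.46, camera adjusted p = 0.0576). With calls up and down, the remaining lists were cell cycle (0 and 1 of 24; 0 adjusted over the list alone; camera adjusted p = 0.729), endoplasmic reticulum stress (2 and 0 of 13; 1 and 0; 0.559), oxidative phosphorylation (0 of 18; 0; 0.418), endothelial markers (0 and 1 of 12; 0; 0.642, median 0.01 and mean -0.23), immediate early and heat shock genes (1 and 5 of 17; 1 and 6; 0.114), mitochondrially encoded genes (0 of 9; 0; 0.193) and ribosomal proteins (0 of 18; 0; 0.559). None of the red blood cell markers could be tested at this age either. Single left-out libraries brought further lists past the threshold: histone lysine methylation enzymes downward without control 2 (camera adjusted p = 0.0334), knockout 2 (0.0269) or knockout 3 (0.01), and immediate early and heat shock genes downward without knockout 3 (0.05). Interferon response genes passed upward without control 1 (0.00879), knockout 1 (0.0112) or knockout 2 (0.00131). Without knockout 1, mesangial and fibroblast (0.00146), inflammatory and NF-kB (0.0036) and actin and adhesion genes (0.0182) passed upward and the tubule list downward (0.0172).

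**Figure D4:**
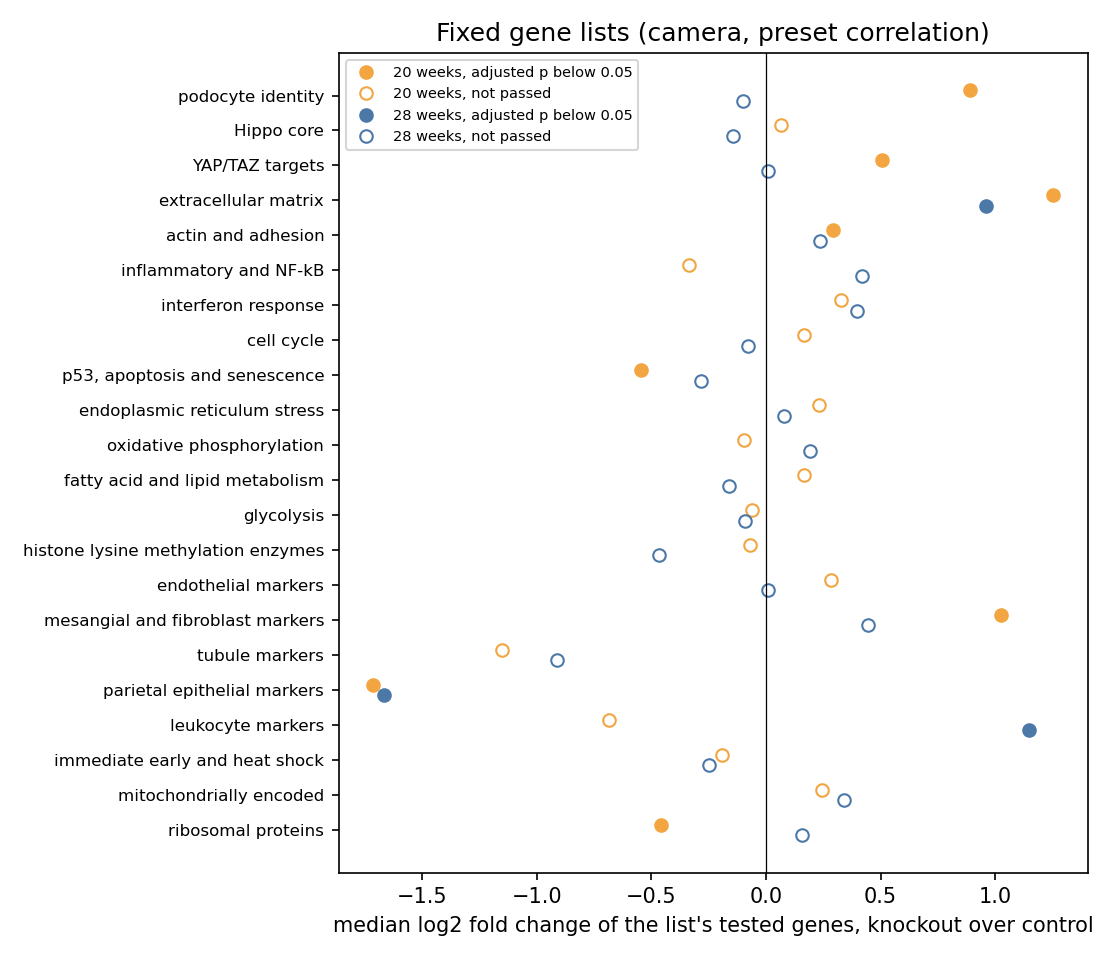
Median log2 fold change (knockout over control) of each fixed gene list at 20 and 28 weeks, 1 point per list and age, filled where the camera adjusted p was below 0.05. Matrix genes lie at 1.25 and 0.96 and parietal epithelial markers at -1.71 and -1.67, all 4 filled, and none of the 4 passed with an estimated correlation (adjusted p = 0.327 at 20 weeks and 0.904 at 28 weeks for both lists).

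At 28 weeks 3183 of 15011 genes tested were called, 1400 higher and 1783 lower, and 5225 had an unadjusted p below 0.05 (edgeR). Of these, 599 were at least 2-fold higher and 1031 at least 2-fold lower. Over all genes tested the groups did not overlap in 6332 (42.2%). Chance gives 10% on average for separate samples, and a higher share if the alike controls 2 and 3 came from 1 animal. Genes are not independent, so a single split can lie far from that average. The count was 1973 without control 1, 1288 without control 2, 1266 without control 3 and 2057 without knockout 2, and 1299 with the alike controls 2 and 3 summed. Of 76 named genes called, 45 stayed called without each library in turn, and no called gene changed sign. Of the 75 besides Nsd2 the fold of 16 moved by over 1.5 times, among them Cldn19 (log2 -6.09 to -7.09), Kcnq1 (-6.17 to -7.88), Sgpp2 and Hpcal4 without knockout 1. Hpcal4 then had 1619 counts over the controls and 3 over the knockouts, a ratio of 294 with an exact 95% counting interval of 100.4 to 1427. Without knockout 3 they included Cdh1 (-4.95 to -5.90), Il5ra (-6.48 to -7.97), Mab21l4 (-6.93 to -8.22) and Ppbp (-6.44 to -7.29).

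The next comparison sets the knockout effects of the ages side by side. Among 14567 genes tested at both ages, 696 were called at both in the same direction and 0 in opposite directions. The 315 genes higher at both ages included Tagln, Acta2 and Fas, and the 381 lower at both included Il5ra, Ppbp and Mab21l4. Of these, the 28-week call was lost under 4 of 17 alternatives for Acta2 and 1 of 17 for Fas. The 20-week call of Mab21l4 was lost under 3 of 15, and the other calls of these genes were kept. Independent lists of these sizes would share 65.9 higher and 87.7 lower genes (Fisher's exact test, two-sided, odds ratio 9.93, 95% interval 8.41 to 11.7, p = 7.72e-145 for higher and 9.88, 8.44 to 11.6, p = 6.37e-166 for lower). These p-values and intervals take genes as independent, which they are not, and do not measure the spread between libraries. Of 1433 genes called at 20 weeks and tested at both ages, 1379 (96.2%) had the same sign at 28 weeks, against 70.1% of all genes. Across genes, which are not independent replicates, Pearson's r of the fold changes was 0.714 and Spearman's rho 0.583. The count at both ages moved by over 1.5 times without 20-week control 1 (192), control 2 (305), knockout 1 (1074), knockout 2 (333) or knockout 3 (265). It also moved without 28-week control 2 (386) or 3 (379) and with those controls summed (384). Further such settings were knockout 1 of both ages left out (1283), the model of 12 libraries (1148) and DESeq2 (1356). The replicate number as a block, given further below, moved it too.

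**Figure D5:**
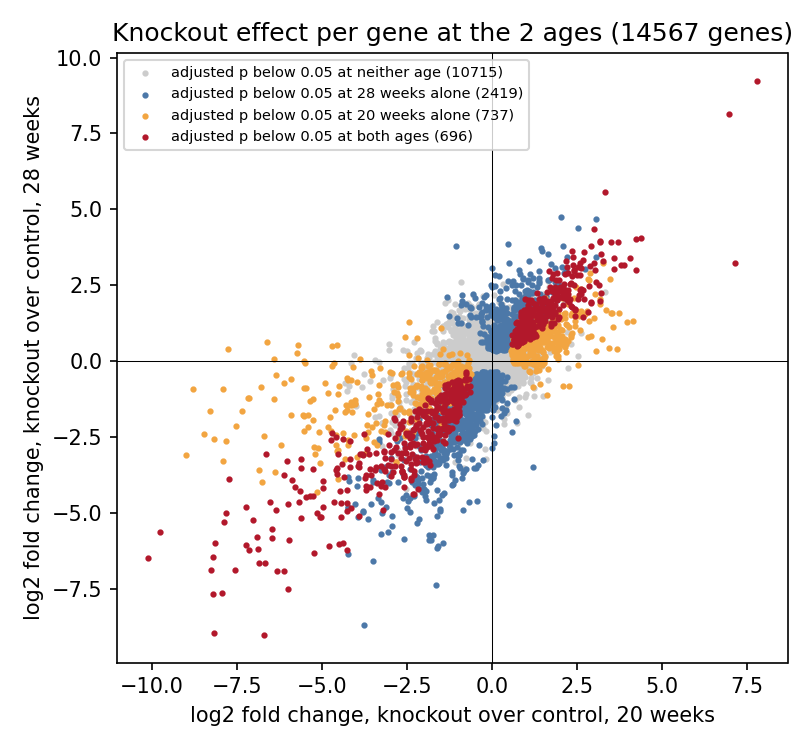
Log2 fold change (knockout over control) at 20 weeks (x axis) against 28 weeks (y axis), 1 point per gene for 14567 genes. Of these, 696 were called at both ages, 737 at 20 weeks alone, 2419 at 28 weeks alone and 10715 at neither.

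Whether the knockout effect changed between the ages was tested directly. No gene of 15662 passed (edgeR; 0 called, 1428 at an unadjusted p below 0.05, smallest adjusted p = 0.538), while DESeq2 called 27. The smallest p belonged to Itga3 (difference of log2 fold changes -1.63, SE 0.30), Tril (-2.69, SE 0.51) and the histone gene H4c8 (1.85, SE 0.36), all with adjusted p = 0.538. Genes called at 1 age alone, such as Wwc1 at 28 weeks or Clic5 at 20 weeks, are thus not shown to differ between the ages. Of 22 lists, 9 passed with camera at the preset correlation, 4 upward and 5 downward, and 0 with an estimated correlation (smallest adjusted p = 0.693 with an estimated correlation; 0 with fry). Podocyte identity genes had a lower knockout effect at 28 than at 20 weeks in 29 of 30 members (median -0.95), and ribosomal protein genes a higher one in 18 of 18 (median 0.63). Leukocyte markers had a higher one in 13 of 13 (median 1.92), but without 20-week control 3 in 8 of 13 (median 0.52), and the list then did not pass (camera adjusted p = 0.0527).

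Change with age was examined within each genotype, where age coincides with the deposited table and any difference in handling between the tables is included. In controls, no gene of 15662 passed (edgeR; 0 called, 466 at an unadjusted p below 0.05, smallest adjusted p = 1.00), and DESeq2 called 1, Smim10l2a (log2 of 28 over 20 weeks 1.61, adjusted p = 0.000938). The smallest p in edgeR belonged to Smim10l2a (1.62, SE 0.30), 1600027J07Rik (-0.88, SE 0.18) and Gm11520 (-1.44, SE 0.30). With camera 8 of 22 lists were higher at 28 weeks: podocyte identity (adjusted p = 0.000569), endothelial (0.000569), cell cycle (0.0168), mitochondrially encoded (0.0168), glycolysis (0.0179), interferon response (0.025), tubule (0.045) and parietal epithelial genes (0.0495). None passed with an estimated correlation (smallest adjusted p = 0.735 with an estimated correlation).

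In knockouts, 0 of 15662 genes passed for age (edgeR; 1759 at an unadjusted p below 0.05, smallest adjusted p = 0.429), and DESeq2 called 40. The smallest p belonged to Gch1, the first enzyme of tetrahydrobiopterin synthesis (log2 1.07, SE 0.18), the acute phase gene Saa3 (7.80, SE 1.32) and the immunoproteasome subunit Psmb8 (1.1, SE 0.20). Without 28-week knockout 1 the test called 1 gene, Saa3 (adjusted p = 0.0334), and without 28-week knockout 2 it called 4, Havcr1, Prr15l, Ston2 and Timd2 (adjusted p = 0.0377 to 0.0425), which were chosen after their values were seen. Lists lower at 28 than at 20 weeks in the knockouts, with camera, were podocyte identity (adjusted p = 2.79e-11), Hippo core (6.63e-06), YAP/TAZ targets (0.000361), matrix (0.00169), histone lysine methylation enzymes (0.00398) and actin and adhesion (0.0489). Higher were ribosomal proteins (5.9e-09), inflammatory and NF-kB (3.86e-06), interferon response (4.54e-05), oxidative phosphorylation (0.000344), leukocyte (0.000361) and mitochondrially encoded genes (0.0111). With an estimated correlation 0 of the 12 passed (smallest adjusted p = 0.405 with an estimated correlation).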

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

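The comparison of gene lists between the ages was chosen after the data had been seen, as were its values without single libraries and the tests on cell sources and on the alike controls. The splits of the libraries were set before.

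In 9 gene lists the knockout effect at 28 weeks differed from that at 20 weeks by camera at the preset correlation. Its adjusted p was 3.31e-13 for podocyte identity (median difference of log2 fold changes -0.95, negative in 29 of 30 genes), 0.00282 for Hippo core (-0.34, 25 of 33), 0.00619 for YAP/TAZ targets (-0.45, 16 of 22), 0.00943 for cell cycle (-0.24, 17 of 24) and 0.00957 for histone lysine methylation enzymes (-0.23, 12 of 14). In the other direction it was 4.88e-08 for ribosomal proteins (0.63, positive in 18 of 18), 0.000382 for leukocyte markers (1.92, 13 of 13), 0.00329 for inflammatory and NF-kB genes (1.11, 18 of 22) and 0.00943 for oxidative phosphorylation (0.28, 15 of 18). With an estimated correlation 0 of the 9 passed (smallest adjusted p = 0.693). Without 20-week control 3, which stood apart in leukocyte genes (Tyrobp 17.9 CPM, 2.23 and 2.34 CPM in the other controls), the leukocyte list did not pass (0.0527, median 0.52, 8 of 13 positive). Hippo core (0.0682), YAP/TAZ targets (0.12) and oxidative phosphorylation (0.172) did not pass without 28-week knockout 1, and inflammatory and NF-kB genes (0.415) and cell cycle (0.227) without 28-week knockout 3. Cell cycle also did not pass without 20-week control 1 (0.107), nor oxidative phosphorylation without 20-week control 2 (0.152) or 28-week control 1 (0.0815). Lists beyond the 9 passed without some single libraries, among them matrix genes downward without 20-week control 3 (0.000516) and interferon response genes upward without 28-week control 1 (0.00566). In the test of single genes the real split called 0, which all 100 splits within the ages reach whatever the data, so this count decides nothing about chance. The highest other split called 2246, a structure of the samples that can be the genotype effect itself, since these splits mix the genotypes.

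Most genes of tubule and other epithelia had lower values and most contractile genes higher ones in the knockouts at both ages, but in 28-week knockout 1 Krt8 (5545 CPM, 111 to 2376 in controls) and Epcam (478 CPM, 229 to 375) lay above every control and Myh11 (2.41 CPM, 3.54 to 8.91) below. A lower share of podocytes in the knockout preparations was predicted to move the contractile and the epithelial junction medians alike. They lay apart by 3.42 (SE 0.485) at 20 weeks and 4.18 (SE 0.448) at 28 weeks. Both lists were written after the calls had been seen and chosen for the pattern, so this gap follows from their choice and cannot decide. Its SE comes from resampling genes, which are not independent replicates. Podocyte identity genes, a list fixed before the data were examined, had medians of 0.89 at 20 weeks and -0.10 at 28 weeks. Whether the podocyte share was lower was not settled by these values. A smaller share of tubule or other epithelial cells in the knockout preparations cannot be told apart from an effect of the genotype: in the tubule and parietal lists, which were not written for this pattern, 13 of 14 members had negative values at 20 weeks (92.9%) and 15 of 17 (88.2%) at 28 weeks, where the share fell short of the bound set for it. Abundant junction genes were uneven between knockouts 1 to 3 at 20 weeks, with Krt18 at 133, 36.5 and 31.6 CPM (controls 1058; log2 -3.98, and -4.95 without knockout 1), Cldn4 at 426, 51.9 and 62.0 CPM (controls 1207) and Krt8 at 980.3, 54.3 and 59.8 CPM (175, 1162 and 1471 in the controls), and Krt7, Krt8, Krt18 and Krt19 also stand in the parietal list, as Cdh1 and Epcam do in the tubule list. An effect of the genotype itself on these genes stays open and was not tested.

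Control libraries 2 and 3 at 28 weeks were much alike. Their mean chi-square of 4.56, against 1 under sampling noise, argues against 1 library listed under both labels. Their BCV of 0.0474, below the 0.228 of the next most alike pair of a group, is compatible with 1 RNA or 1 animal possibly having been prepared as both libraries. No biological explanation was tested.

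Of 13 leukocyte markers 3 were called higher in the knockouts at 28 weeks. More leukocytes in the knockout preparations might be the source. Of the tested members 92.3% had positive values (12 of 13, median log2 fold change 1.15, bootstrap SE 0.247 over genes, which are not independent replicates). This recounts the values that gave the pattern, so it cannot decide between sources. Csf1r, a receptor gene of macrophages, was the exception at -0.49 (SE 0.31), and the members did not move together in each library: in knockout 3 Lyz2 was highest (785 CPM), but C1qb (7.17 CPM) lay below controls 2 and 3 (10.8 and 10.3 CPM). Lyz2 was the most abundant member, at 651 CPM in the knockouts, and Adgre1 was at 7.31 CPM. An effect of the genotype within podocytes stays open as untested.

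Splits of the libraries regardless of genotype were counted for the other results. The splits at 1 age were too few for a share under 0.05: of 10 splits, 1 called as many genes as the real one at 20 weeks (real 1473, highest other 0) and 1 at 28 weeks (3183, 0), and 5 and 10 gave as many lists (8 against 13, and 3 against 15). The list splits mix the genotypes, whose effect can enter those counts, though this was not tested. At 28 weeks every other split passed more lists (6 to 15) than the real split (3). List counts at the preset correlation thus do not set the genotype apart from other groupings of these libraries. For age the real count was 0 in controls and in knockouts, which all 10 splits reach whatever the data (highest other 0 and 32), so these counts decide nothing. For genes called at both ages, of 100 pairs of splits 1, the real one, reached 696 (highest other 0). Each other split called 0 genes at its own age, so every pair holding such a split had to give 0. The pairs thus restate the gene counts at the single ages, whose splits were too few, and do not decide about chance. They show only that the real split alone gave calls at each age. The alike controls at 28 weeks may also not be separate samples.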

How the results depend on the processing

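Counting controls 2 and 3 at 28 weeks as their sum and leaving out knockout 1 were chosen after the data had been seen, as were single lists without 1 library; all other settings were set earlier. Of 2847 values of 178 named results under alternatives, 2427 kept direction and side of the threshold, 363 were no longer past it, 35 came past it and 22 reversed; 170 results never reversed, and the 22 reversals were of genes not called at that age. At 20 weeks, DESeq2 called 2430 genes, and leaving out 1 library gave 517 to 2023. At 28 weeks the count was 1630 with at least a 2-fold change, 1299 with controls 2 and 3 summed, 1003 with knockout 1 also left out, and 1266 to 3374 without 1 library. Lists past the threshold fell to 0 at both ages with an estimated correlation. With fry they were 7 at 20 weeks, against 8 with camera at the preset correlation, and 0 at 28 weeks. Also at 28 weeks they were 10 without a filter, 7 in the model of 12 libraries, 7 with the summed controls and knockout 1 left out, and 3 to 8 without 1 library. Genes called at both ages numbered 1356 with DESeq2, 1148 in the model of 12 libraries, 384 with the summed controls, 1283 with knockout 1 of both ages left out, and 192 to 1074 without 1 library. DESeq2 called 27 genes for the change of the knockout effect, 1 for age in controls and 40 for age in knockouts, and leaving out 1 library gave 0 to 4 for the last. Nsd2 at 20 weeks was not past the threshold with the 1 CPM filter (-0.93), and ranged from -1.01 to -0.72 without 1 library. Fewer libraries leave fewer residual degrees of freedom; otherwise the cause was not tested. Replicate numbers did not pair the samples (correlations of same-numbered deviations -0.13, 0.30 and -0.20 at 20 weeks and -0.55, -0.08 and -0.44 at 28 weeks). With the replicate number as a block, 332 genes were called at 28 weeks and 1164 at 20 weeks, 187 at both ages, 6 lists passed at 28 weeks, and Nsd2 at 28 weeks (-1.12) was not past the threshold. Reversed log2 values were, at 20 weeks, Nphs1 -0.0299 with the 1 CPM filter and -0.0025 in the model of 12 libraries. At 28 weeks they were Lats2 0.0095 with the median of ratios, 0.036 with the upper quartile, 0.0095 with DESeq2 and 0.060 with the summed controls and knockout 1 left out, and Synpo -0.14 with the summed controls. Without 1 library the ranges were Nphs1 -0.36 to 0.57, Lats1 -0.27 to 0.16 and Stk3 -0.039 to 0.51 at 20 weeks, and Lats2 -0.25 to 0.24, Ccn1 -0.37 to 0.24, Podxl -0.59 to 0.11, Synpo -0.23 to 1.09 and Yap1 -0.051 to 0.43 at 28 weeks. Medians of lists that reversed ranged, without 1 library, from -1.19 to 1.14 for leukocyte markers at 20 weeks, and at 28 weeks from -0.015 to 0.44 for actin and adhesion, -0.30 to 0.19 for Hippo core and -0.39 to 0.92 for inflammatory and NF-kB genes. At totals of 31405349 to 38989180 counts, a count of 0 in a library allows a level of up to 0.0769 to 0.0955 CPM.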

Other observations

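The gene described here was chosen after its values had been seen. Among genes called higher in the knockouts, 5 at 20 weeks and 7 at 28 weeks had at most 3 counts over the 3 controls, and 2 of them did at both ages. Prm1, which encodes a protamine of sperm chromatin, had 1 count in the controls and 291 in the knockouts at 20 weeks (ratio 308, exact 95% counting interval 54.9 to 12210), with 1.66 to 3.36 CPM per knockout library. At 28 weeks it had 0 and 198 counts, at least 81.4-fold higher with a floor of 3 counts over the group, and 1.29 to 3.46 CPM per knockout library. Parts of the Prm1 gene serve as the tail of some Cre transgenes, and the construct of these mice was not given in the sources used here.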
